A study of Homo sapiens with 6 samples.

How the data were processed

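Circular RNA (circRNA) was profiled by RNA sequencing in HaCaT cells, an established line of human keratinocytes. Per the labels, 3 libraries came from sham-irradiated cells and 3 from cells exposed to UVA at 5 J per square centimetre, with RNA isolated after 6 h. The labels' protocols name TRIzol for the extraction and RNase R, a nuclease that digests linear RNA, at the step they describe as removal of ribosomal RNA. Per the series' design text, the reads were aligned to hg38, and reads crossing a back-splice junction were used to identify and measure each circRNA. The submitters' processing notes name the builds hg38 and GRCh38. The aligner, the circRNA caller, their versions and the annotation are not given in the sources used here.

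Each library has 1 deposited table with an identifier, an expected count and a TPM value per circRNA. The expected counts that the authors deposited are estimated numbers of reads per circRNA and are not scaled. They were whole numbers apart from 1 to 4 circRNAs per library, and the smallest listed value was 2 reads in each of the 6 tables. A circRNA missing from a table therefore had no listed value and was set to 0, although it could hold 1 read, or more if the calling dropped it for another reason. The deposited TPM values are called TPM by the file headers and the labels. They equalled the expected count times 1 constant per library, to within a relative tolerance of 1e-06, for all but 37 to 112 circRNAs per library (0.446% to 0.587% of those listed), so they behave as reads scaled to a fixed library total, with no scaling by length. In those exceptions the TPM was up to 2.26 times the value that the count gives. The constants imply library totals of 64555 to 361024 reads. The listed circRNAs held 84.9% to 86.3% of these totals, and the remaining reads were not analysed here. The files do not pair the identifiers with gene names or positions, so host genes, the gene lists fixed beforehand, genomic spans and exon ends were not analysed here, and no genome or annotation was used.

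The design fixed before the data were examined named limma on log2 TPM for files without counts and edgeR for files with counts. Because the files held expected counts, edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) was the main test. Counts were rounded to whole numbers, circRNAs listed in at least 3 of the 6 libraries were tested, library sizes were scaled by TMM, and the 2 groups were compared with no covariate. The TMM factors were highest in the libraries with the lowest totals, 1.27 in UVA replicate 1 and 1.13 in sham replicate 2. In the others they were 0.860 to 0.965. Over circRNAs listed in all 6 libraries they were 0.968 to 1.04. The test was two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are given as the deposited TPM, as mean ± SD of 3 libraries. They are relative to each library's own total, so the amount of circRNA per cell was not measured. Standard errors of log2 fold changes were the fold change divided by the square root of the test statistic. For a circRNA with no reads in 1 group, the fold was set against a floor of 3 reads over that group's summed library totals. It is a lower bound only if an unlisted circRNA holds at most 1 read per library. That is not shown, because listed circRNAs held 84.9% to 86.3% of the totals at each depth and the other reads were not traced. Intervals and floors cover counting error only where no replicate enters them, and the reads carry no molecular identifiers in the files used here. The number of circRNAs listed and the share of the 10 most abundant, ranked in each library on its own, were compared by exact two-sided permutation tests. These used the 20 relabellings of 3 against 3, which cannot give a p below 0.1. Because depth differed between libraries, each library was also thinned by binomial sampling to 64555 reads, counting circRNAs with 2 or more reads, as a mean of 20 thinnings.

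The alternatives were other filters, median-ratio scaling, DESeq2 1.42.0, limma 3.58.1 on log2(TPM + pseudocount), the replicate number as a block, and each library left out in turn. The limma pseudocount was 31.0 TPM, the largest over the libraries of the 5th percentile of listed values, with 7.75 and 1 TPM tried beside it. Chosen after the data were seen were limma at its own main pseudocount, 1 read in place of 0 for unlisted circRNAs, library totals without TMM, robust dispersion, and the 2 libraries under 100000 total reads as a covariate or left aside. That pair was noticed on the first principal component and among the most abundant circRNAs, and the limit of 100000 reads was set afterwards, so it is not a batch named by the labels. The rule for named circRNAs took the 8 higher and 8 lower with the smallest p, the 6 most abundant, and the 3 most abundant per direction that were listed in 1 group alone. As the identifiers carry no gene, at most 2 per direction are printed, and the others are described by their values.

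The main test was tested on simulated counts with the real mean levels and library totals and the median dispersion of circRNAs listed in all 6 libraries (0.0616), in which 200 circRNAs were changed and single reads were left unlisted. Of the 11039 simulated circRNAs that passed the filter, 93 were called and 0 of these were unchanged ones. Among circRNAs listed in all 6 real libraries, 0 of 25 changed by 2-fold, 17 of 25 changed by 4-fold and 23 of 25 changed by 8-fold were called. Among those listed in fewer libraries, 1 of 25 changed by 4-fold, 9 of 25 changed by 8-fold and 18 of 25 changed by 16-fold were called. That dispersion lies below the common dispersion of 0.361 in the fit of all 12615 circRNAs. With the trended dispersions of that fit (median 0.725), 9345 circRNAs passed the filter and 67 were called, 2 of them unchanged ones. Among circRNAs listed in all 6 libraries, 0 of 25 were then called at 2-fold, 13 of 25 at 4-fold and 16 of 25 at 8-fold, and among the others 0 of 25 at 4-fold, 5 of 25 at 8-fold and 9 of 25 at 16-fold.

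No 2 libraries were alike within sampling noise, with a chi-square per degree of freedom of at least 1.58 over the 15 pairs. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which could be technical.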

Results

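The study asked which circRNAs differ in HaCaT keratinocytes 6 h after a UVA dose of 5 J per square centimetre, with sham-irradiated cells as the control. CircRNAs are closed loops of RNA made when a downstream splice site joins an upstream one, and they are counted through the reads that cross this back-splice junction. There were 3 sham and 3 UVA libraries. The totals behind their TPM values were 229393, 91053 and 154628 reads in sham replicates 1 to 3. In UVA replicates 1 to 3 they were 64555, 173641 and 361024 reads. Depth here means these totals, and the number of reads sequenced was not used. The mean total was 158358 ± 69245 reads in sham and 199740 ± 149948 in UVA (SD, n = 3 each). One read was worth 2.77 TPM in the deepest library and 15.5 TPM in the shallowest. The precision therefore differed between libraries, and the smallest listed value of 2 reads stood for a different level in each.

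HaCaT cells held a broad set of circRNAs in both groups, and its size did not differ detectably after UVA. In all, 26209 circRNAs were listed in at least 1 library. Of these, 3472 (13.2%) were listed in all 6 libraries, and they carried 68.0% of the listed reads. Another 8530 (32.5%) were listed in a single library and carried 2.89% of the reads. Sham libraries listed 11973 ± 3500 circRNAs and UVA libraries 13004 ± 6206 (SD, n = 3 each), a difference of 1031 (exact permutation p = 0.9, two-sided). With every library thinned to 64555 reads the difference was -35.55, with 7288 ± 318 circRNAs in sham and 7252 ± 491 in UVA (exact permutation p = 0.9). Without thinning it was -757 with sham replicate 2 left out and -2013 with UVA replicate 3 left out. The smallest p this design allows is 0.1.

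**Figure D1:**
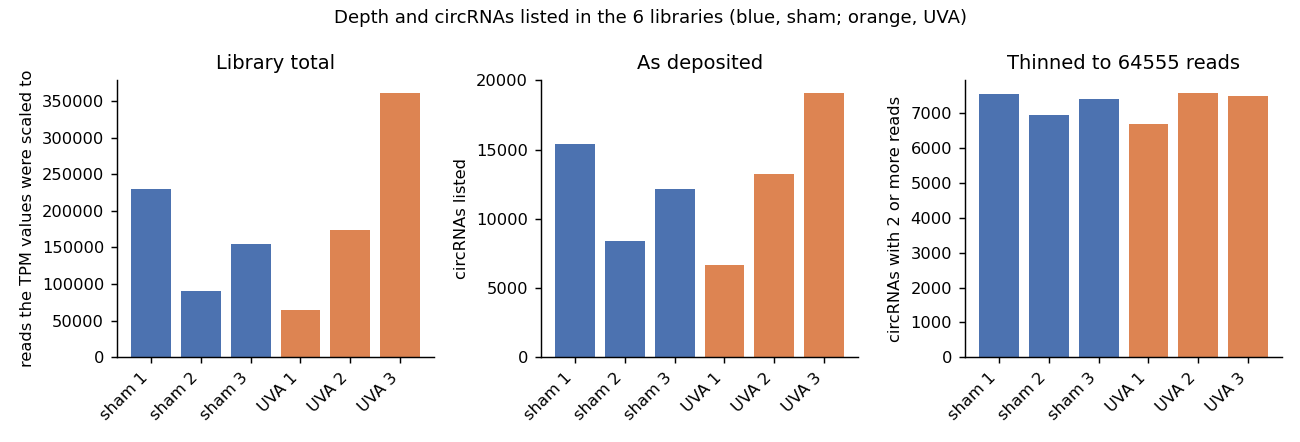
Reads that the TPM values were scaled to (left), circRNAs listed (middle) and circRNAs with 2 or more reads after thinning to 64555 reads (right), 1 bar per library. The listed number followed depth, from 6687 in UVA replicate 1 to 19092 in UVA replicate 3, and lay between 6687 and 7573 after thinning.

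The most abundant circRNAs took similar shares of the reads in the 2 groups. TPM and the test scale each library to its own reads, so a change of all circRNAs together would not be seen. The top circRNA was at 6299 ± 1155 TPM in sham and 6867 ± 850 TPM in UVA, a log2 fold change of 0.13 ± 0.22 (SE). The next was at 5574 ± 506 TPM in sham and 5803 ± 247 TPM in UVA (SD, n = 3 each). The third and the fourth varied widely within groups, at 4435 ± 2315 and 4150 ± 2261 TPM in sham against 4613 ± 1149 and 4074 ± 1227 TPM in UVA. The fifth was at 3807 ± 833 TPM in sham and 3781 ± 764 TPM in UVA, and the sixth at 3922 ± 1074 and 3612 ± 1090 TPM. None of the 10 most abundant was called, and the largest absolute log2 fold change among them was 0.14 (edgeR quasi-likelihood test, adjusted p = 1.00 for each). The 10 most abundant circRNAs of each library took 4.88% ± 0.233 of the summed TPM in sham and 4.83% ± 0.241 in UVA (exact permutation p = 0.8, two-sided). These were ranked in each library on its own and can differ from the 10 above.

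The test called 4 of the 12615 circRNAs tested, each of them lower after UVA. A split that mixed the treatments, sham replicates 1 and 3 with UVA replicate 1 against the others, called 6. The number of calls thus does not set treatment apart from other groupings. No circRNA rose past the threshold, nor did any with DESeq2, while some alternatives called higher ones. On log2 TPM, limma called 1 higher and 3 lower after quantile scaling, and 8 higher and 6 lower with weights for libraries. In edgeR 3 higher and 2 lower were called with the 2 shallowest libraries left aside. The fold bounds here and below assume that an unlisted circRNA holds at most 1 read per library. The call with the smallest p was novel_circRNA_16735, at 179 ± 58.7 TPM in sham (18 to 35 reads per library) and unlisted in all 3 UVA libraries. It was at least 33.2-fold lower under that assumption (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.20e-09). The next, novel_circRNA_1969, was at 110 ± 28.9 TPM in sham and also unlisted in UVA, at least 21.9-fold lower (adjusted p = 0.000423). The third called circRNA was at 87.8 ± 23.3 TPM in sham and unlisted in UVA, at least 16.4-fold lower (adjusted p = 0.0304). Without UVA replicate 3, the deepest library, these 3 bounds fell to 13.2-fold, 8.69-fold and 6.52-fold. The fourth did not separate the groups library by library. It was at 371 and 453 TPM in sham replicates 1 and 3 and unlisted in sham replicate 2, while UVA replicate 1 held 418 TPM and the other 2 UVA libraries did not list it (log2 fold change -1.93 ± 0.44, edgeR quasi-likelihood test, adjusted p = 0.0305). Without UVA replicate 1 it was at least 58.1-fold lower (adjusted p = 4.58e-07). It was not called without sham replicate 1, sham replicate 3, UVA replicate 2 or UVA replicate 3, with log2 fold changes of -1.57, -1.36, -1.17 and -1.06. Over the 20 alternative fits that tested it, the adjusted p ran from 2.01e-17 to 1.00.

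On the higher side, the 8 circRNAs with the smallest p included 3 with no listed reads in sham, and none of the 8 was called. The smallest p was that of novel_circRNA_49508, which was listed in sham replicate 2 at 264 TPM and in UVA replicates 2 and 3 at 369 and 191 TPM, and was unlisted in the other 3 libraries (adjusted p = 0.598). Next came novel_circRNA_48396, at 73.8 ± 57.0 TPM in UVA (8 to 13 reads per library) and unlisted in sham (adjusted p = 0.791). It was at least 7.93-fold higher against the floor of 3 reads over the sham group, and at least 4.10-fold higher without sham replicate 1. On the lower side, 5 of the 8 circRNAs with the smallest p were unlisted in all UVA libraries. The best of the 4 uncalled ones was at 65.3 ± 41.5 TPM in sham and unlisted in UVA (adjusted p = 0.791). At an unadjusted p under 0.05 there were 245 circRNAs, where 631 would be expected by chance from uniform p-values.

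**Figure D2:**
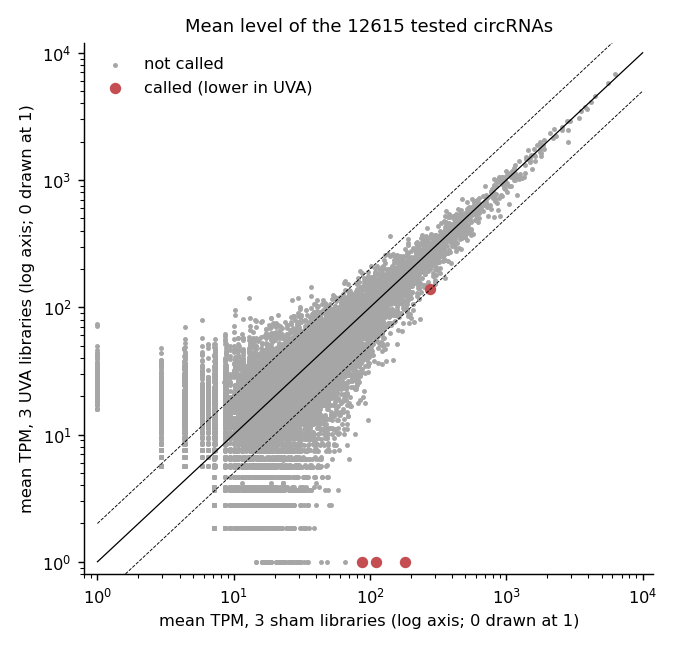
Mean TPM of each tested circRNA in the 3 sham libraries (x axis) and the 3 UVA libraries (y axis), both on log axes with 0 drawn at 1; the solid line marks equal levels and the dashed lines 2-fold differences. Abundant circRNAs lie near the line, and the 4 called circRNAs (red) lie below it, 3 of them with no listed reads in UVA.

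**Figure D3:**
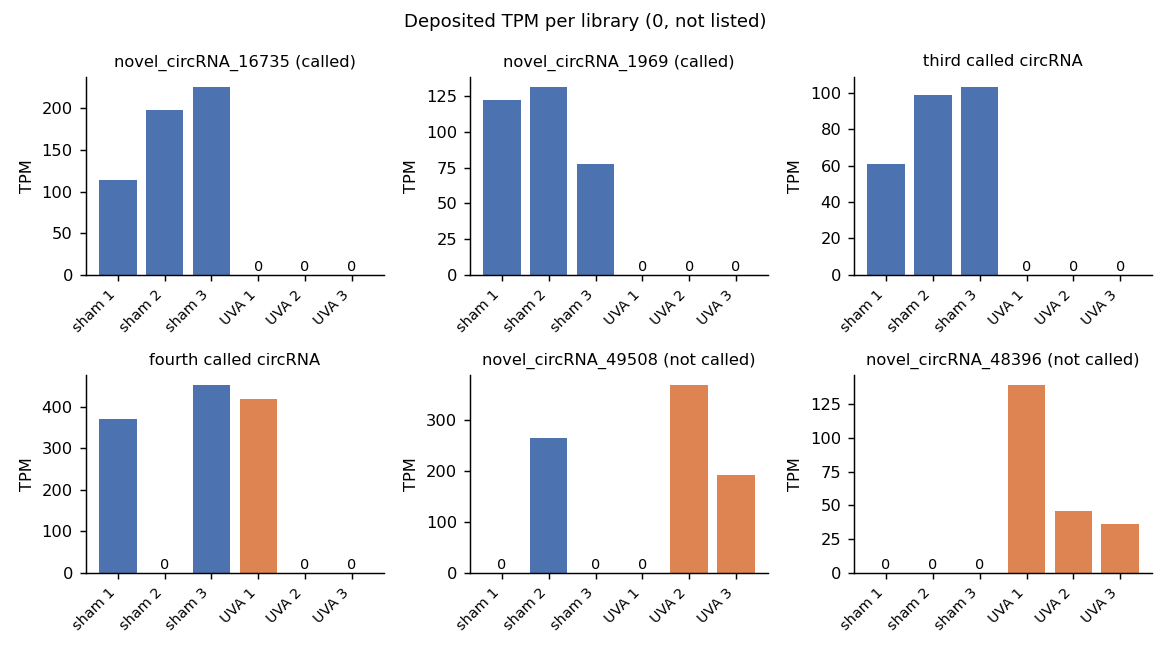
Deposited TPM in each library (blue, sham; orange, UVA) of the 4 called circRNAs and of the 2 with the smallest p on the higher side, which were not called. The first 3 called circRNAs are listed in 3 of 3 sham libraries and 0 of 3 UVA libraries, while the fourth is listed in UVA replicate 1 and missing from sham replicate 2.

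Among the 4 called circRNAs the support was uneven. Across 20 alternative fits that tested them, novel_circRNA_16735 was called in 19 (adjusted p from 2.93e-10 to 0.945, edgeR, DESeq2 and limma) and novel_circRNA_1969 in 16 (7.27e-05 to 0.945). The third and the fourth were each called in 6, and novel_circRNA_49508 in 3, among them the fit without sham replicate 2 (adjusted p = 1.71e-10, the lowest of a range that reached 1.00). That fit leaves out the only sham library that listed it. Without sham replicate 1, novel_circRNA_1969 was at least 19.5-fold lower and was not called (adjusted p = 0.163). The count of calls was 2 without sham replicate 1, 2 without UVA replicate 2 and 8 without UVA replicate 3. With unlisted circRNAs set to 1 read, 4 circRNAs were called, the same 4. DESeq2 called 2, both among the 4.

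For circRNAs measured in every library, most fitted changes were small. A circRNA unlisted throughout 1 group cannot enter this set. Over the 3472 listed in all 6 libraries and fitted on their own, the median log2 fold change was 0.0016, the median absolute value 0.26, and the 5th and 95th percentiles -0.73 and 0.70. The extremes were -2.24 and 1.85. None passed the threshold (edgeR quasi-likelihood test, 103 at an unadjusted p under 0.05). In the same fit, the 95% interval of the fold change lay inside a 2-fold change either way for 1115 of these 3472, and in the fit of all 12615 circRNAs for 791. For the rest of the 3472 in each fit the interval reached a change of that size.

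Some circRNAs were listed in all 3 libraries of 1 group and in none of the other. There were 55 listed in sham alone and 111 in UVA alone, 166 together. They were rare, with a median of 10 reads over the 3 sham libraries and 11 over the 3 UVA libraries. The 3 most abundant on the sham side were the first 3 called circRNAs above. On the UVA side the 3 most abundant were at 73.8 ± 57.0, 71.8 ± 85.6 and 49.9 ± 10.7 TPM, the first being novel_circRNA_48396, and none was called. After thinning to equal depth the balance turned round, with 89.7 in sham alone and 78.3 in UVA alone as means of 20 thinnings.

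Libraries did not group by treatment. Over the 3472 circRNAs listed in every library, log2 levels correlated at a mean Pearson r of 0.817 within groups (0.765 to 0.887, 6 pairs) and 0.825 between groups (0.771 to 0.900, 9 pairs). These are correlations across circRNAs, which are not independent replicates. The first principal component held 38.1% of the variance and set sham replicate 2 (25.1) and UVA replicate 1 (31.5) apart from the other 4 libraries (-19.4 to -4.34). These were the 2 libraries with fewer than 100000 reads, a limit set after the pair was seen. On the second component (21.6%) the same 2 libraries lay at opposite ends, at -28.3 and 25.1. Their correlation with each other was 0.785, below the 0.810 of sham replicate 2 with sham replicate 3 and the 0.794 of UVA replicate 1 with UVA replicate 3. By chi-square per degree of freedom they were instead the closest of any pair, at 1.58 against 2.09 and 2.48 for those pairs. Both measures depend on depth, so neither settles how alike the libraries were. Setting them against the other 4 called 131 of the 3472 circRNAs, 42 higher and 89 lower, with median log2 fold changes of 1.12 and -1.42. The third and the fourth most abundant circRNAs were among those lower, with log2 fold changes of -1.36 ± 0.13 and -1.35 ± 0.13 (SE). The pair was noticed on the first component and among the most abundant circRNAs of these same data. These calls therefore describe the difference and are not an independent test of it. Each other choice of 2 libraries called 0 to 2 of the 3472. Over all 12615 tested circRNAs the pair called 122 and the other choices 1 to 13, the highest being sham replicate 3 with UVA replicate 1.

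**Figure D4:**
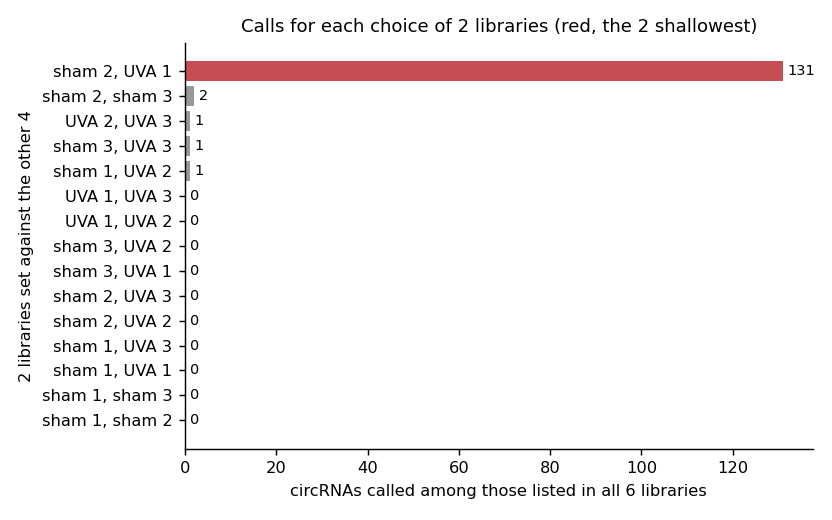
Number of circRNAs called (x axis, adjusted p under 0.05) when each of the 15 choices of 2 libraries (y axis) was set against the other 4, over circRNAs listed in all 6 libraries. The pair of sham replicate 2 and UVA replicate 1, the 2 shallowest libraries, gave 131 calls, and the other choices gave 0 to 2.

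Because each group held 1 of these 2 libraries, the treatment could be compared with the pair as a covariate. That fit called 2 circRNAs, novel_circRNA_16735 (adjusted p = 3.49e-05) and novel_circRNA_1969 (adjusted p = 0.00546), both lower after UVA. Within the 4 deeper libraries, 2 against 2, 5 circRNAs were called, 3 higher and 2 lower, of which 2 were among the original 4. There novel_circRNA_16735 was called (at least 28.3-fold lower, adjusted p = 0.00712), and novel_circRNA_1969 was not (at least 18.6-fold lower against 21.9-fold in all 6 libraries, adjusted p = 0.0865), while novel_circRNA_49508 was called higher (adjusted p = 0.00106). The fourth of the original 4 was called lower (edgeR quasi-likelihood test, adjusted p = 7.35e-05). For these last 2 circRNAs, the libraries left aside were the ones that went against the rest of their group. Their separation here thus follows from which libraries were removed. The 2 shallow libraries alone leave 1 library per group and no test.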

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

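The number of circRNAs called between UVA and sham was small under each setting tried, and it moved by more than 1.5 times in several. Against 4 with the settings of the report, no filter called 8 (2 higher, 6 lower; 3 of the main 4) and a filter on circRNAs listed in all 6 libraries called 0 (103 at an unadjusted p under 0.05). DESeq2 called 2. On log2 TPM, limma called 7 at its main pseudocount, 4 with quantile scaling (2 of the main 4), 9 at 7.75 TPM, 0 at 1 TPM (419 at an unadjusted p under 0.05) and 14 with weights for libraries (8 higher, 6 lower). With robust dispersion 2 were called, and 2 with the 2 shallowest libraries as a covariate. These 2 settings, limma at its main pseudocount, 1 read for unlisted circRNAs, library totals without TMM and the 2 shallowest libraries left aside were chosen after seeing the data. Leaving out 1 library at a time gave 2 to 8 calls, with 2 without sham replicate 1, 2 without UVA replicate 2 and 8 without UVA replicate 3. Median-ratio scaling (4), 1 read for unlisted circRNAs (4), library totals without TMM (3) and the 2 shallowest libraries left aside (5) stayed within 1.5 times. Without TMM the fourth of the main 4 was the one not called (edgeR quasi-likelihood test, adjusted p = 0.258). With the replicate number as a block, 3 were called, 2 of them among the main 4. Same-numbered libraries deviated from the group means with correlations of -0.263, -0.152 and 0.0265, which gives no sign of pairing. Deviations cancel within each group, and sham replicate 2 and UVA replicate 1 deviated together (0.264), so a weaker pairing could be hidden. The difference in circRNAs listed turned to -35.55 after thinning and ranged from -2013 (without UVA replicate 3) to 4189 (without UVA replicate 1) with 1 library left out, and was -757 without sham replicate 2. The difference in the share of each library's own 10 most abundant ranged from -0.168 (without UVA replicate 2) to 0.0846 (without sham replicate 1) percentage points. It was 0.0733 without UVA replicate 3. CircRNAs listed in 1 group alone fell from 166 to 108 with values under the pseudocount set to 0. No host gene, gene list, span or exon-end alternative was run, and libraries were not left out of the count of circRNAs listed in 1 group alone. The cause of these shifts was not tested. In counts simulated at the dispersion of circRNAs listed in all 6 libraries, 10 times the depth raised the calls among those circRNAs from 0 to 5 of 25 at 2-fold and from 17 to 25 of 25 at 4-fold, and among the others from 1 to 24 of 25 at 4-fold, with 6 of the 166 calls at that depth false ones. No deeper simulation used the wider dispersions of all tested circRNAs, so the gain from depth at that spread is not known.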

Other observations

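All tests in this part were chosen after the patterns were seen, and for each except the removal of the 10 most abundant circRNAs its result, or values close to it, had also been seen.

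For the difference of the 2 shallowest libraries (sham replicate 2 and UVA replicate 1) from the other 4, sampling of fewer reads was set against the data by thinning every library to 64555 reads. A median of 44 circRNAs (26 to 69 over 5 thinnings) was still called for the pair, against a median of at most 1 and at most 8 in a single thinning for any other choice of 2 libraries, so equal depth did not remove the difference. The thinned fits kept the circRNAs listed in all 6 libraries at full depth, so an effect of depth on that choice was not removed. The number of thinnings was raised from 1 to 5 after the result of the first was seen. A few dominant circRNAs do not account for it, since the 10 most abundant took 3.79% to 4.37% of each library total, which shifts all others by at most 0.00868 on the log2 scale, against a median absolute log2 fold change of 1.38 for the 131 calls; without these 10, 115 of the 131 calls remained, short of the 90% set beforehand for this test, but 6 of the 131 were themselves among the 10, a comparison made after the value was seen. Of the 15 choices of 2 libraries, 1 gave as many calls as this pair (131, highest other 2), and 15 choices are too few for a share under 0.05. No biological explanation was tested, as UVA is not shared by the pair, and a preparation that differed in input, RNase R digestion or day may have lowered the yield and shifted these circRNAs, which the labels do not record.

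Some circRNAs switched between many reads and none. In 82 of 3390 circRNAs that could show it, a library listed no value where the libraries that did list the circRNA predicted 20 or more reads, 124 cases in all (14 in sham replicate 3 to 38 in UVA replicate 3). The same count on 100 simulated data sets gave 0.11 cases (0 to 2) at the dispersion of circRNAs listed in all 6 libraries. It gave 52.9 (32 to 73) at the common dispersion of all tested circRNAs and 103 (73 to 125) with their trended dispersions. Read sampling with the first, small spread between libraries thus gave far fewer cases than the 124 seen, but that spread came from circRNAs that show no such case. The wider dispersions were estimated from counts that hold these cases, so a wide spread between libraries stays open. The set as a whole did not follow treatment more than other splits. Of the 82, 59 were unlisted in libraries of both groups and 23 in libraries of 1 group alone (17 UVA and 6 sham), where the other 9 splits of the libraries gave up to 27 and up to 19 on 1 side. Any unlisted library counted here, also 1 with fewer than 20 predicted reads, so the 59 can hold circRNAs missed at low depth. A response to UVA in part of the set is not excluded. Fully along the 2 groups were 4 of the 82, and other splits gave up to 4. Only 2 of the 82 had a circRNA within 3 identifier numbers with the opposite pattern, and 100 shuffles gave up to 2, so the numbers are not shown to follow position and reads assigned to a neighbouring circRNA stay open. The authors' calling of each circRNA per library, which may drop or keep a junction as a whole, was not tested. Each of the 4 circRNAs called between sham and UVA has this same form, the fourth with 27 to 85 reads where listed. In the alternative fits nearly all calls were unlisted in at least 1 library, with 12 of 14 under limma weights and 4 of 5 without UVA replicate 1. In the remaining fits that made calls, each call was unlisted somewhere. Only 3472 of the 12615 tested circRNAs were listed in all 6 libraries, so most tested circRNAs were also unlisted somewhere. Being unlisted in a library thus does not by itself set the calls apart.

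The count of calls itself was set against other groupings. Of the 10 splits of the 6 libraries into 3 and 3, 2 gave 4 or more calls. The real one gave 4, and that of sham replicates 1 and 3 with UVA replicate 1 gave 6. The fourth called circRNA was listed in these 3 libraries alone, so its listing followed that split and not treatment. For circRNAs listed in all 3 libraries of 1 side and none of the other, 10 of the 10 splits gave at least the 166 of the real one, with a highest other of 999, in the split of sham replicate 1 with UVA replicates 2 and 3, the 3 deepest libraries. With 10 splits no share under 0.05 is possible.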
